A study of Glycine max with 6 samples.

How the data were processed

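RNA-seq libraries were made from soybean (Glycine max, strain KF1) hairy roots, the transformed roots that grow out of a stem after injection with Agrobacterium rhizogenes. Per the labels' protocols, seedlings grew at 28 °C with 16 h of light and 8 h of dark. Strain K599 of the bacterium was injected 2 cm above the soil, and roots of 2 to 10 cm were harvested. Total RNA was extracted with a phenol-based reagent (TRNzol), and libraries were prepared with an Illumina RNA-seq kit. The labels place the 6 libraries in 3 groups of 2: a construct that overexpresses GmPHD6, a construct that silences it by RNA interference (RNAi), and a control with K599. Nothing in the labels says whether the 2 libraries of a group came from separate plants.

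The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the number of fragments sequenced) with a lower and an upper confidence bound and a text flag of the estimate for each of 56044 gene models. Per the file headers there is 1 value per gene and condition, so the 2 libraries of a group had been combined by the authors before deposit, and no SD, n or test across libraries can be given for these columns as they stand. TopHat, a splice-aware aligner, is named in the submitters' processing notes. Its version, the quantification tool, the confidence level of the bounds and the strand setting are not given in the sources used here. The deposited gene IDs carry the tag of the soybean annotation Wm82.a2.v1, and coordinates are printed as deposited; whether starts count from 0 or 1 is not stated. The column labelled G6 was read as short for GmPHD6 and taken as the overexpression group, since the other 2 columns carry the names of the RNAi and control groups.

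No gene names are paired with the IDs in the deposited table, and 0 IDs matched the RefSeq table of assembly Glycine_max_v4.0 used as reference. The 49 gene lists fixed before the data were examined were written as gene descriptions, so 0 of them could be matched. For the same reason the level of GmPHD6 itself was not analysed here. At most 2 IDs are named per direction, those with the largest log2 difference among genes past the fold rule with at least 5 FPKM in the higher column; sets of genes changed by both constructs are ranked by the smaller of the 2 differences.

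The design fixed beforehand was limma over 6 libraries, with named genes taken from its calls. With pooled columns it was replaced by a rule of size. Genes entered with an OK flag in the 3 columns and at least 1 FPKM in at least 1 column, which left 33291. A difference is log2(FPKM + 1) of one column minus that of another, so it understates the change of low genes. A gene passed the fold rule with an absolute difference of at least 1 (2-fold on this scale) and authors' bounds that did not overlap. Genes listed at 0 in either column compared got no fold, because an exact 0 can be a failed estimate. The rule is not a test across replicates and gives no p-value. On simulated columns with counting error alone, it called 95.0% of 200 genes changed 4-fold and 12.0% of 200 changed 2-fold between overexpression and control among the 31996 and 32014 genes tested, with 0 unchanged genes called.

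The width of the bounds gave the depth. If the bounds lie 2 standard deviations of counting error from the value, the fragments behind each value can be computed. Summed over genes they came to 14636610 fragments per library for overexpression, 15319043 for RNAi and 15201221 for control. The bounds lay about 30.8%, 30.3% and 28.3% from the value at 1 to 3 FPKM and 1.45%, 1.45% and 1.54% above 1000 FPKM. They narrow with level as counting error does, and do not include the spread between plants.

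For genes with few fragments the computed means fell on sums of whole multiples of 2 step sizes per column, as an average of whole fragments in 2 libraries of unequal depth would. The nearest sum was accepted within 0.75 of the rounding error where chance would match under 0.05 of values. This placed 69.2% of 12816 overexpression values, 69.8% of 13548 RNAi values and 71.1% of 13038 control values, against 0.741%, 0.694% and 0.683% of shifted values. On simulated pairs of libraries 99.6% of recovered pairs were right. In each pair the library with the smaller step is called A and the other B. Which one is replicate 1 is not known. Recovered genes hold at most about 38 fragments on average.

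For 3036 genes recovered in the 3 columns with a mean of at least 5 fragments, limma (version 3.58.1 in R 4.3.3) was fitted to log2(fragments + 1) of the 6 libraries with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. A value listed at 0 entered as 0 fragments. These p-values measure the spread between these libraries, which may be technical. On simulated data of the same 3036 genes, 55 of 200 genes changed 4-fold and 133 of 200 changed 8-fold were called for overexpression against control, and 41 and 145 for RNAi against control. The scale and the filter of this fit, the recovery rule, the windows along chromosomes and all use of recovered fragments were chosen after seeing the data.

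Windows of 15 consecutive tested genes with an absolute median difference of at least 1 were merged into regions. The median of each region was placed among 10000 random gene lists of the same size matched on mean expression; since the regions were picked for their medians, this describes the columns and is not a test. Runs of at least 3 neighbouring genes past the fold rule in the same direction were compared with 100 shuffles of the gene order. For contrasts that share the control column, 20 simulations of unchanged groups were made with counting error alone, and 20 with the spread between libraries measured in recovered genes. That spread came from genes of 5 to 20 fragments and was applied to tested genes of every level, though it was not measured in higher ones. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the pseudocount, the filter, quantile and TMM scaling, the bounds, gene span, overlapping genes and the size of the fold, and for limma also the trend, robust estimation, the groups in the fit and each library left out.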

Results

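The data set described gene expression in soybean hairy roots carrying a GmPHD6 overexpression construct, a GmPHD6 RNAi construct or, as control, K599, with 2 libraries per group. GmPHD6 is an Alfin-like protein with a PHD finger, a domain that binds histone tails in many proteins. Whether it does so in GmPHD6 was not examined here. The submitters defined genes downstream of GmPHD6 as those higher with overexpression and lower with RNAi. Each group was available as the authors' pooled FPKM per gene, so values are printed with the authors' bounds and without replicate error. Between 31065 and 31320 genes reached 1 FPKM in each column. The FPKM columns summed to 833516 for overexpression, 753999 for RNAi and 676881 for control. The 50 highest genes took 28.5% of the sum in overexpression, 14.2% in RNAi and 16.96% in control. Across the 33291 tested genes, which are not independent replicates, log2 values correlated with Pearson's r of 0.960 between overexpression and control, 0.900 between RNAi and control and 0.889 between the 2 constructs. None of the 455 gene models on 127 unplaced scaffolds passed the filter on flag and level, so all 33291 tested genes lie on chromosomes.

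Overexpression was compared with control to ask which transcripts differ with the construct made to raise GmPHD6, whose own level was not analysed. In the overexpression column 279 genes were higher and 453 lower past the 2-fold rule, 2.20% of those tested. Genes listed at 0 in a column compared got no fold and could not pass. Of genes with at least 1 FPKM in both other columns, 29 were listed at 0 in control and 49 with overexpression. Among genes past the rule the steepest rise was at Glyma.08G250300 on chromosome 8 (21883791 to 21885282). It stood at 184 FPKM (bounds 176 to 192) against 1.11 in control (0.515 to 1.70), a log2 difference of 6.46. Glyma.09G068500 on chromosome 9 (6937813 to 6941687) stood at 689 FPKM (677 to 702) against 6.92 (5.86 to 7.97), a difference of 6.45. Among lower genes, Glyma.06G043000 on chromosome 6 (3285791 to 3287447) read 0.127 FPKM (0 to 0.295) against 17.6 (15.8 to 19.4), and Glyma.11G042000 on chromosome 11 (3060730 to 3067543) read 1.11 (0.749 to 1.48) against 26.7 (25.1 to 28.4). Their log2 differences were -4.05 and -3.71, and -6.29 and -4.47 with log2(FPKM + 0.1). The median difference over all tested genes was 0.02 and the SD 0.41.

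Of the 279 higher genes, 46 lay in one stretch of chromosome 13 between 3083566 and 4226773, where 47 genes were tested. The stretch runs from the first to the last of these 46 genes, so their share of its tested genes is partly set by that choice. Together these 46 genes held 161148 FPKM in overexpression, 19.3% of the column, against 15352 in control and 21925 in RNAi, that is 10.5 times the control sum with overexpression and 1.43 times with RNAi. Of the fragments computed from the bounds they held 10.3% with overexpression, 1.44% with RNAi and 1.21% in control. Their median level was 1714 FPKM with overexpression and 106 in control, and 8 of the 10 highest values of the overexpression column belonged to them. Their log2 differences from control ran from 1.03 to 4.53 with a median of 3.16. With RNAi the median difference of these genes was 0.45, and none of the 46 passed the rule. The window scan drew the region wider, from 2621543 to 6068823, with 61 genes that had a fold; 46 were higher, 0 lower, and the median of 2.55 exceeded every one of 10000 random lists, whose most extreme median was 0.21 in size. The wider region's median was 1.86 after quantile normalization, 1.45 without the filter on low values, and 3.16 with genes of at least 5 FPKM. Of the 46 genes, 16 share a locus with another gene model, so the split of fragments among them is uncertain.

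**Figure D1:**
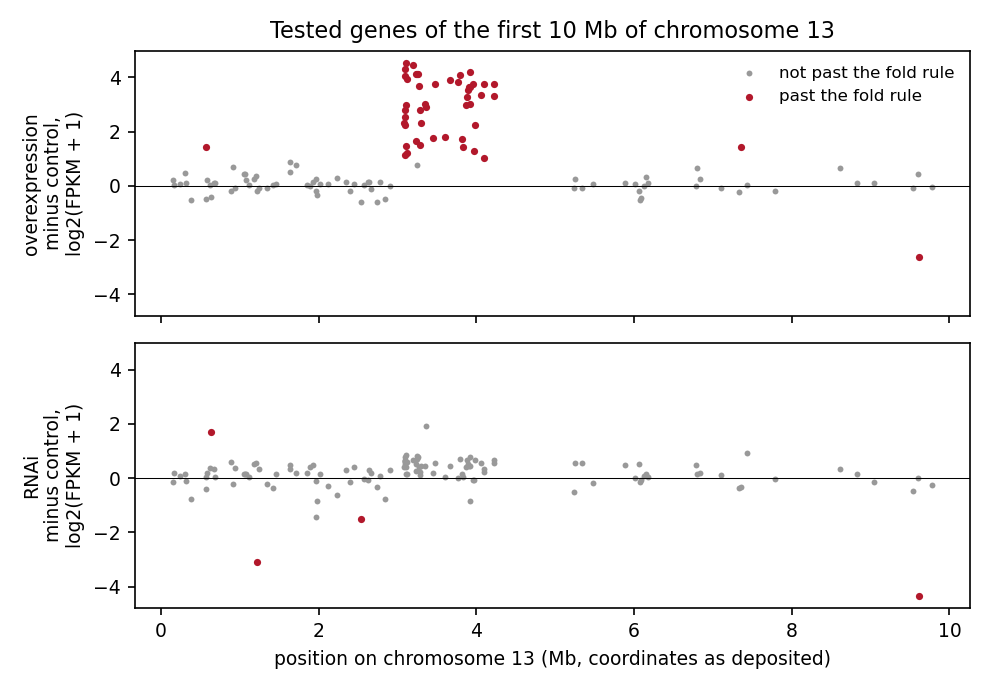
Each point is a tested gene in the first 10 Mb of chromosome 13, with its position in Mb on the x axis and its log2(FPKM + 1) difference from control on the y axis, for overexpression above and RNAi below; red points passed the fold rule. The 46 red points between 3083566 and 4226773 in the upper panel reach from 1.03 to 4.53, and none of those genes is red in the lower panel.

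Outside that stretch, overexpression had 8 further runs of at least 3 neighbouring genes past the rule. The 10 runs in all compare with a mean of 0.09 in shuffled gene order. On chromosome 11, 5 genes between 9858538 and 9893357 were lower, with a median log2 difference of -2.36 and a summed level of 24.8 FPKM against 147 in control. On chromosome 15, 6 genes between 13467901 and 13545084 were higher with a median of 1.65, at a summed 32.0 FPKM against 3.61. A run of 4 genes on chromosome 17 between 5028346 and 5042804 was lower, with a median of -1.42, and stood at 153 FPKM in RNAi against 56.7 in control and 19.2 in overexpression.

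Simulated unchanged groups were also made for overexpression against control. With the spread between libraries measured in low genes they gave 808 genes past the rule on average, against 732 observed. With counting error alone they gave 0.20. The first simulation applied the spread of genes of 5 to 20 fragments to genes of every level, where it was not measured. It therefore does not show how many of the 732 genes would pass without a change. With log2(FPKM + 0.1) the rule gave 443 higher and 814 lower genes.

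RNAi was compared with control to ask which transcripts differ with the construct made to silence GmPHD6. The rule gave 1836 higher and 1847 lower genes, 11.1% of those tested and 5.03 times the number for overexpression. Among these genes Glyma.08G250300, highest in fold with overexpression, was also highest, at 472 FPKM (459 to 485) against 1.11 in control. Its log2 difference was 7.81. Glyma.11G121800 on chromosome 11 (9303964 to 9305430) stood at 313 FPKM (304 to 322) against 2.84 (2.04 to 3.63), a difference of 6.36. Glyma.20G184800 on chromosome 20 (42290006 to 42290628) read 2.53 FPKM (1.40 to 3.66) against 127 (119 to 135), and Glyma.10G006900 on chromosome 10 (678248 to 679163) read 20.8 (17.9 to 23.7) against 602 (587 to 616). Their differences were -5.18 and -4.79. The SD of the differences over all tested genes was 0.71 around a median of 0.05. Higher genes made up 3.57% of genes under a mean of 3 FPKM and 13.3% of genes of 100 FPKM or more, and lower genes 4.17% and 6.86%. These means include the RNAi column, so a gene higher with RNAi is placed at a higher level. Low genes also pass the rule less easily, so the trend with level is partly built in. In simulated unchanged groups with the spread of low genes applied at every level, 535 genes passed the rule on average. With genes of a mean of at least 5 FPKM the rule gave 1207 lower genes.

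**Figure D2:**
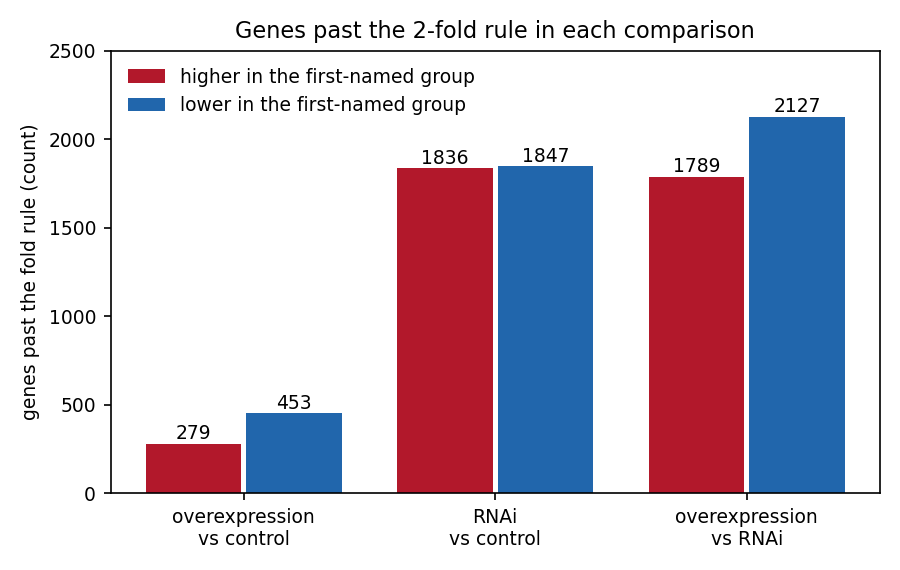
Bars give the number of genes past the 2-fold rule in each comparison, higher in red and lower in blue. Overexpression against control has 279 and 453 genes, RNAi against control 1836 and 1847, and overexpression against RNAi 1789 and 2127; pooled columns give no error bars.

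Genes past the rule with RNAi also lay next to each other. There were 55 runs of at least 3 neighbours, 33 higher and 22 lower, with 186 genes; shuffled orders gave a mean of 10.6 and at most 18. Of these 186 genes, 5.38% share a locus with another gene model. Copies at separate loci that share fragments were not looked for in these runs, nor in the overexpression runs outside the chromosome 13 stretch. On chromosome 7, 5 genes between 16580991 and 16599084 were higher with a median log2 difference of 3.71, at a summed 615 FPKM against 49.5 in control and 48.5 in overexpression. On chromosome 12, 6 genes between 5089678 and 5114869 were lower with a median of -2.12, at 10.5 FPKM against 69.8 in control and 74.5 in overexpression. On chromosome 13, 4 genes between 36262125 and 36271624 were lower with a median of -3.09, at 51.7 FPKM against 509. On chromosome 6, 4 genes between 48741425 and 48752673 were lower with a median of -2.56, at 23.1 FPKM against 208.

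The window scan marked 3 wider regions for RNAi. On chromosome 8 between 8337999 and 8543885, 10 of 20 genes were higher and 1 lower, with a median log2 difference of 0.99 that 0 of 10000 random lists reached. On chromosome 7 between 16399177 and 16876805, 10 of 24 were higher and 1 lower, with a median of 0.44 that 20 of the random lists reached. On chromosome 12 between 5035419 and 5217887, 8 of 18 were lower and 1 higher, with a median of -0.52 that 2 reached. In the overexpression column the medians of these regions were -0.13, -0.11 and 0.04.

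The 2 constructs were also compared directly. Overexpression was higher than RNAi at 1789 genes and lower at 2127. Glyma.15G211500 on chromosome 15 (32692487 to 32693522) read 40.8 FPKM (37.4 to 44.2) with overexpression, 0.234 (0 to 0.484) with RNAi and 24.7 in control. Glyma.15G062800 on the same chromosome (4817476 to 4818233) read 60.5 (55.3 to 65.7), 1.04 (0.394 to 1.70) and 37.9. In the other direction, Glyma.13G186200 on chromosome 13 (29990951 to 29993554) read 0.912 (0.497 to 1.33), 141 (136 to 146) and 1.57, and Glyma.17G049900 on chromosome 17 (3785987 to 3788223) read 0.345 (0.0910 to 0.598), 72.2 (68.6 to 75.7) and 1.58. Log2 differences between the constructs were 5.08 and 4.91, and -6.22 and -5.77. Each of these 4 genes passed the rule for RNAi against control. For overexpression against control none reached a difference of 1 on the log2(FPKM + 1) scale, which understates low genes. The bounds with overexpression nevertheless lay above those in control for Glyma.15G211500 (22.3 to 27.1 in control) and Glyma.15G062800 (34.1 to 41.8), and below them for Glyma.17G049900 (1.08 to 2.07).

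Genes that answered the submitters' definition, higher with overexpression and lower with RNAi than in control, numbered 28. Glyma.10G224300 on chromosome 10 (45503641 to 45505214) read 32.7 FPKM (29.4 to 36.0) with overexpression, 1.53 (0.810 to 2.25) with RNAi and 8.85 (7.30 to 10.4) in control. Glyma.09G179700 on chromosome 9 (40465340 to 40466129) read 60.4 (52.7 to 68.1), 5.50 (3.23 to 7.77) and 19.3 (15.4 to 23.2). The mirror set, lower with overexpression and higher with RNAi, held 94 genes, led by Glyma.07G212400 on chromosome 7 (38389880 to 38390911) at 4.37 FPKM, 136 FPKM and 24.03 FPKM and by Glyma.02G132500 on chromosome 2 (13731473 to 13732535) at 0.309 FPKM, 28.9 FPKM and 4.997 FPKM, in the same order of columns. With log2(FPKM + 0.1) the 2 sets held 47 and 169 genes, and at a 4-fold rule 0 and 4.

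Genes that moved the same way with both constructs were more numerous: 65 were higher in both and 146 lower in both. Glyma.08G250300 led the higher set, followed by Glyma.17G117200 on chromosome 17 (9234325 to 9235375) at 21.9 FPKM with overexpression, 34.0 with RNAi and 0.521 in control. Glyma.06G043000 and Glyma.11G042000 led the lower set, at 0.232 and 2.81 FPKM with RNAi. Independent lists of these sizes would share 15.6 genes in the submitters' direction, 24.9 in its mirror, 15.3 higher in both and 25.3 lower in both. Simulated unchanged groups with the spread of low genes applied at every level gave 0.15, 0.10, 23.3 and 25.6, and 0 in every set with counting error alone. Part of the excess in the same-direction sets can come from the shared control libraries, and the controls are too few to split with 2 libraries in each part.

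**Figure D3:**
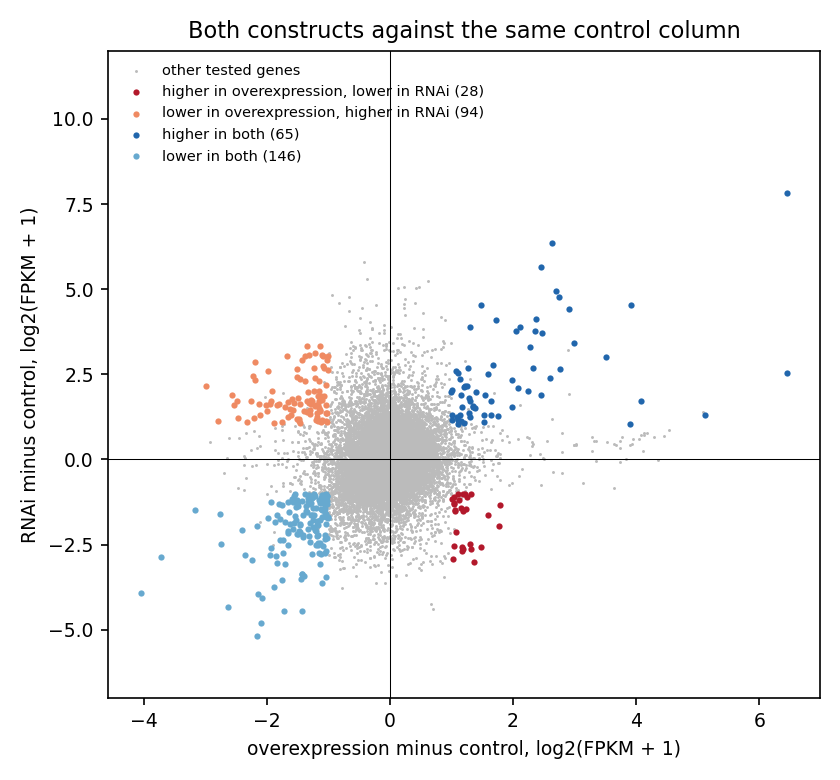
Each point is a tested gene, with the log2(FPKM + 1) difference of overexpression from control on the x axis and that of RNAi from control on the y axis. Coloured points passed the fold rule in both comparisons: 28 higher with overexpression and lower with RNAi, 94 the reverse, 65 higher in both and 146 lower in both.

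Over 32883 genes with a fold in both comparisons, the differences from control correlated with Pearson's r of 0.172 and Spearman's rho of 0.190 across genes. Unchanged groups sharing the control gave an r of 0.334 with the spread of low genes applied at every level and 0.498 with counting error alone. The observed covariance was 0.0494, beside simulated values of 0.0618 and 0.00957.

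Fragments per library could be recovered for genes of low level, which allowed a test across libraries for 3036 genes. Only 25 of the 732 genes past the fold rule for overexpression and 57 of the 3683 for RNAi are among them. Most genes past the fold rule were therefore not tested across libraries. By limma with Benjamini-Hochberg adjustment, 1 gene differed between overexpression and control, 34 between RNAi and control (2 higher and 32 lower) and 73 between the constructs (45 higher and 28 lower with overexpression). At an unadjusted p under 0.05 there were 266, 463 and 562 genes, where chance gives 151.8. The scale and filter of this fit were chosen after seeing the data. Those first designed gave 4, 9 and 16 genes, and no filter gave 0 in each comparison. With only the 2 constructs in the fit, 0 genes differed between them. The 73 therefore depend on a spread estimated jointly with the control libraries, and this comparison was not among those simulated. The single overexpression gene, named after its values were seen, was Glyma.19G218100, listed at 0 with overexpression, with 37.8 and 15.1 recovered fragments in control and an adjusted p of 0.0185. A value listed at 0 can be a failed estimate, and this call rests on reading it as 0 fragments. Of the 34 and 73 genes, 7 and 20 were listed at 0 in 1 of the groups compared; without genes listed at 0 in any column limma called 0, 29 and 55. Recovery stops near 38 fragments, so genes that rose beyond it are missing from these counts.

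These calls rested on few libraries: without control library A or without control library B, limma called 0 genes in each of the 3 comparisons. Without overexpression library A the counts were 1, 67 and 10, and without B 0, 69 and 116. Without RNAi library A they were 0, 32 and 14, and without B 0, 11 and 13. Between libraries of a group, the coefficient of variation beyond counting error in genes of 5 to 20 fragments was 41.1% for overexpression, 36.8% for RNAi and 26.5% for control.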

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

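The settings on bounds, gene span, shared loci, the chromosome 13 region and a 4-fold rule, and for limma the pseudocounts, the 10-fragment filter and leaving out genes listed at 0, were tried after seeing the data. Of 451 recomputed differences of named genes 0 changed sign and 0 fell under 2-fold, and 24 moved by over 1.5 times, each with a smaller pseudocount (Glyma.06G043000 from -4.05 to -6.29 with log2(FPKM + 0.1)). Only the pseudocounts, quantile normalization and TMM scaling can alter a gene's difference. Under the other settings it was unchanged by construction, so most of the 451 were no check. Of 110 recomputed counts of the fold rule, 91 stayed within 1.5 times. RNAi kept more genes than overexpression under each of the 11 settings, from 4.03 times with log2(FPKM + 0.1) to 6.62 times at 4-fold. With log2(FPKM + 0.1), which gives low genes larger differences by construction, overexpression had 443 higher and 814 lower genes, and the joint sets held 47 (submitters' direction), 169 (mirror), 122 (higher in both) and 320 (lower in both). With log2(FPKM + 0.5) 233 genes were lower in both. A mean of at least 5 FPKM, which tests fewer genes, left 1207 genes lower with RNAi and 87 lower in both. The 4-fold rule left 75 and 50 genes for overexpression, 459 and 368 for RNAi, 363 and 633 between constructs, and 0, 4, 20 and 11 in the joint sets. The correlation of the 2 contrasts was 0.195 with log2(FPKM + 0.1), 0.183 with log2(FPKM + 0.5), 0.114 with the 5 FPKM filter and 0.195 after quantile normalization; the cause was not tested.

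The limma counts, 1 for overexpression, 34 for RNAi and 73 between constructs, moved more. The scale first designed, log2(FPKM + 1) with at least 1 FPKM in 2 libraries, gave 4, 9 and 16 genes. RNAi and the construct comparison gave 19 and 21 with log2(fragments + 0.5), 81 and 121 with log2(fragments + 4), and 85 and 177 at an adjusted p under 0.1. Without genes listed at 0 in any column the overexpression count was 0. Without a filter all 3 counts were 0, and with at least 10 fragments 0, 13 and 18. Quantile normalization gave 105 for RNAi. The planned TMM scaling was run in a simplified form, an unweighted trimmed mean of log ratios to 1 control library, and moved no count by over 1.5 times. Without the mean-variance trend the overexpression and RNAi counts were 0 and 66, and with only the 2 groups compared they were 0 and 73, with 0 between constructs. Leaving out each library in turn gave 0 to 1, 0 to 69 and 0 to 116; the group left with 1 library is assumed to vary like the others. The cause of these moves was not tested.

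No paired analysis was possible because the columns carry no replicate numbers. Count-based tools were left out, since the deposited unit is FPKM and fragments were recovered for low genes alone, and the set tests were not run because 0 of the lists matched. Depth limits low genes: bounds lay about 30% from the value at 1 to 3 FPKM.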

Other observations

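The tests in this part were chosen after the patterns were seen; the tests of separation between RNAi and control libraries and of separate control libraries were written before their own results were known.

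Within the chromosome 13 stretch, 3 of the 35 higher genes that share no locus with another of the 46 had exactly the same span of 892, and their levels nearly coincided: 1706 to 1750 FPKM with overexpression, 163 to 168 with RNAi and 98.0 to 99.4 in control. In genes with 1 recovered fragment, libraries A and B of a group differed in number: 364 against 894 genes for overexpression, 1048 against 435 for RNAi and 746 against 770 for control.

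The largest coordinated difference, the chromosome 13 region in overexpression, was weighed against 3 technical explanations. Normalization of the whole column would lift other genes as well, and their median log2 difference was 0.0155 against 2.55 in the region. A contribution of only 1 overexpression library stays open: in 32 region genes with recovered fragments, library B held 67.9% of 252 overexpression fragments against 45.8% elsewhere, and 5 of the 7 genes with at least 10 fragments had more in B, but the spread between genes was not tested and 0 of the 46 higher genes could be recovered; in the region against elsewhere, library B held 63.5% against 50.4% for control and 41.7% against 47.5% for RNAi, so the libraries cannot be told apart for the genes that carry the pattern. Copies that share fragments could spread 1 abundant transcript over many gene models; 8.57% of those 35 genes had a partner of the same span, above the 4.55% that marks the upper 5% of random stretches but far from a majority, and spans are a poor measure of sequence identity. An effect of the construct remains possible and untested, as does RNA carried over from a repeated sequence, since no genome sequence was used here.

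RNAi had 5.03 times as many genes past the rule as overexpression, and depth is argued against, as the RNAi column rested on 1.05 times the fragments of the overexpression column. A larger spread between RNAi libraries is not what genes of 5 to 20 fragments showed, with a coefficient of variation of 36.8% against 41.1% for overexpression. The SD of the differences from control was larger for RNAi under 3 FPKM too, at 0.58 against 0.38. Tested genes under 3 FPKM are not the same set as genes of 5 to 20 fragments. Their spread between libraries was not measured as a set, so this SD cannot be told apart from such a spread. For genes of higher level no values per library were recovered. SDs of 0.90 against 0.44 at 30 to 100 FPKM and 0.98 against 0.76 from 100 FPKM cannot be told apart from it either. A single divergent RNAi library also stays open: both RNAi libraries lay beyond both control libraries in 96.5% of the 57 recovered genes past the fold rule, but these were picked by that fold, overexpression gave 96.0% of 25, and over all 3036 recovered genes the shares were 49.97% and 40.3%, where random order gives 33.3%. A broader response to the RNAi construct than to the overexpression construct is a hypothesis that these columns leave open.

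More genes moved the same way with both constructs than in opposite ways, 211 against 122. Over all tested genes the covariance of 0.0494 lies between the 2 simulated values for a shared control, so that explanation cannot be told apart from a shared response there. The 3036 recovered genes are a different set, with recovered fragments per library in place of pooled FPKM. Their covariances are not comparable in size with 0.0494. In these genes the covariance was 0.313. It was 0.150 (bootstrap SE 0.0235) when one contrast used control library A and the other B, against -0.00999 in simulated unchanged groups. Chance values of the control libraries may therefore account for part of the covariance in low genes. The remainder stayed above 0 with separate control libraries, though with only 2 of them its SE cannot measure the spread between control libraries. Genes listed at 0 in control, however, read 0 in both of these libraries and can add to the remainder. Such a 0 can be a failed estimate, and no covariance without these genes is given here, so the source of the remainder is not settled. A shift common to both constructs relative to the control, biological or from handling the control apart, is a candidate explanation that was not separated further.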
